A study of Mus musculus with 5 samples.

How the data were processed

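RNA sequencing of polyA-selected RNA from C57BL/6 mice was analysed in 5 libraries. The 2 granulocyte libraries came from Gr1+ bone marrow cells of 12-month-old animals and are described by the submitters as technical replicates of 1 biological replicate, so their mean was used and n = 1. The other 3 libraries came from KSL cells, a bone marrow population of c-Kit+, Sca-1+ and lineage-negative cells that holds blood stem and early progenitor cells. Per the labels, Sca-1+ cells of mice given 5-fluorouracil, which kills dividing blood cells, were transduced with a retrovirus that marks cells with green fluorescent protein. They were cultured for 2 days with 10 ng/ml stem cell factor and 100 ng/ml thrombopoietin and then sorted as KSL cells carrying the marker. One virus was a knockdown control and the other two were directed against the long non-coding RNAs LncHSC-1 and LncHSC-2, with 1 library per group. B cell libraries named in the series design were not analysed here.

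The submitters' processing notes name the mouse genome build mm9 and DESeq; the aligner, the counting tool and the release of the gene annotation are not given in the sources used here. Per the file headers, the KSL tables give an FPKM value and a count value for each of 38166 features. The KSL count columns as deposited were treated as a signal, reads multiplied by 1 factor per library, because 91.7% to 92.1% of the values worth up to 20 reads were whole multiples of 1 step within 0.1 of a read. That step, the value of 1 read, was 1.08 in the control library, 0.924 in the LncHSC-1 library and 1.03 in the LncHSC-2 library. Dividing by it gave estimated depths of 21018390, 24145370 and 19934537 reads. These reads are estimates read from the values, and no count test was run on them. The granulocyte count columns as deposited were treated as a score, whole numbers made by multiplying reads by a library factor and rounding; the first value that replicate 1 never takes is 8. The granulocyte FPKM values as deposited equal that score per kilobase with a divisor of 50 M reads in both files, whatever the depth of the library. Estimated depths of the granulocyte libraries were 37.9 M and 46.7 M reads.

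FPKM was the main measure, as scaled by the authors. Median-of-ratios factors of the 3 KSL libraries were 1.00, 0.996 and 1.00 for FPKM, so no further scaling was applied. The same factors of the deposited count columns were 1.04, 1.03 and 0.938, which places the typical gene of the LncHSC-2 library at −0.14 on the log2 scale against control; count columns were therefore used only as an alternative, as deposited and after centring. For each feature with a mean FPKM of at least 5 over the 3 libraries, the log2 ratio of FPKM + 1 was computed, which understates the change of low genes. This floor kept 9153 features, of which 7944 were named genes, 748 carried symbols of predicted, microRNA, small nucleolar, mitochondrial or clone type, and 461 were unnamed transcript models. A difference of 2-fold was used as a rule of size. With 1 library per group no test of a difference between conditions was possible, so no p-value is given. Exact binomial 95% intervals of the ratio of estimated reads, at the relative depth given by reads per FPKM, accompany single genes. These intervals carry no pseudocount, cover counting error only and compare libraries, not conditions. Where a library held no read, a floor of 3 counts gave the bound of the fold.

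Before the data were examined, 24 gene lists of blood cell types, stem cell genes, cell cycle, stress, signalling and metabolism were fixed. The median log2 ratio of each list was placed among those of 10000 random lists of the same size drawn from 20 bins of mean level, and lists outside the central 95% are named. This describes the libraries and is not a test, since genes of a list vary together. Lists of unrelated genes would lie outside by chance in 1.2 of 24 cases, which is no benchmark for lists whose genes vary together. Because both knockdown ratios use the same control library, their correlation, covariance and overlap were also computed in 100 simulated data sets without any effect, with Poisson noise and with the spread of the 3 libraries taken as if replicates.

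The genes named in the text follow a rule fixed before the data were examined, which leaves out the predicted and unnamed features listed above. It takes the 8 highest and 8 lowest genes of each knockdown against control, the 5 highest and 5 lowest in both, the 5 highest and 5 lowest of LncHSC-1 against LncHSC-2, up to 4 members of each list discussed, the 12 highest granulocyte genes with up to 4 members per list, and Kit, Ly6a, Ly6e and Tcf3. Some genes that the rule takes are not reported here. Features outside it are said to have been chosen after their values were seen. Gene positions are those of the files, in mm9.

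For the 3′ UTR scan in the closing section, the longest annotated 3′ UTR of at least 30 bases was taken by gene symbol from GENCODE transcripts of a later mouse genome build, for 7805 of the 7944 named genes. Each of 15860 sequences of 7 bases present in at least 50 genes was scored by the mean log2 deviation of its genes in 1 library from the other two, corrected for UTR length and GC content and given as a z. The bar was the lowest z in each of 100 shufflings of genes. To count carriers among the most changed genes, the 2 lowest sequences were chosen in 1 of 2 random parts of the genes, with at least 25 genes per sequence, and looked up in the other part. The procedure was tested on simulated data: 100 of 100 genes changed 4-fold were called, 0 of 7744 unchanged genes passed 2-fold, 6 of 100 unchanged lists lay outside the central range, 100 of 100 raised lists lay above it, and 10 of 10 implanted sequences were recovered. The simulated reads held counting noise only and the simulated lists were random genes, so these counts are no error rates for the real libraries. Each implanted sequence was given an effect well beyond the bar, so its recovery says nothing about weaker ones. Alternatives were median-of-ratios and trimmed mean of M values scaling, pseudocounts of 0.1 and 5, floors of 0, 1 and 20 FPKM, the mean of a list in place of its median and each granulocyte replicate alone. The deposited count columns with a floor of 50 and a pseudocount of 10, as deposited and centred, and the removal of genes with a control library 7-base sequence were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.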

Results

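Transcript levels were measured by RNA sequencing in Gr1+ bone marrow granulocytes and in transduced blood stem and progenitor cells of C57BL/6 mice. The granulocyte sample was sequenced as 2 technical replicates with totals of 40414961 and 40394825 rounded counts. The 3 KSL libraries, 1 each for the control, LncHSC-1 and LncHSC-2 knockdown viruses, had scaled count totals of 22629745, 22306188 and 20529584. FPKM was at least 5 for 9108, 9150 and 9133 features of these libraries. There was no replicate of any KSL group, so every difference given for them is a difference between 2 libraries that may be technical or biological.

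The granulocytes expressed the granule and antimicrobial genes of neutrophils at very high levels. S100a9 and S100a8, the subunits of calprotectin, stood at 60707 and 56391 FPKM (means of 2 technical replicates, n = 1), and the top 2 features took 6.28% and 6.44% of the counts of the replicates. Ngp was at 11439, Retnlg at 10047, the lysozyme gene Lyz2 at 7953, Lcn2 at 6344, Camp at 5033 and lactoferrin, Ltf, at 4896 FPKM. The gelatinase gene Mmp9 was at 2097 and Anxa1 at 1994 FPKM, and the actin-related genes Tmsb4x and Actb completed the highest 12 at 6568 and 4190 FPKM.

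All 36 genes of the mature granulocyte list and 19 of the 20 primary granule and myeloid progenitor genes were at 5 FPKM or more. The receptor for granulocyte colony-stimulating factor, Csf3r, was at 802 FPKM. In contrast 0 of 21 B lineage genes reached 5 FPKM, the highest being Bank1 at 4.08 FPKM, and 1 of 30 T and NK lineage genes did, Cd3d at 6.56 FPKM. Of 51 stem cell genes 10 reached 5 FPKM, among them Txnip at 333 FPKM and Lmo2 at 24.03 FPKM. Early response genes were also present, with Zfp36 at 369, Fos at 162 and Junb at 152 FPKM. Prg2, an eosinophil granule gene, was at 61.9 FPKM, and the alpha globin feature Hba-a1,Hba-a2 was at 90.8 FPKM. Of 34 mitosis genes 23 reached 5 FPKM, with Mki67 at 35.0 FPKM, and of 32 DNA replication genes 13 did. Of 30 monocyte, macrophage and dendritic genes 17 reached 5 FPKM, among them Mpeg1 at 200 and Csf1r at 57.8 FPKM.

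**Figure D1:**
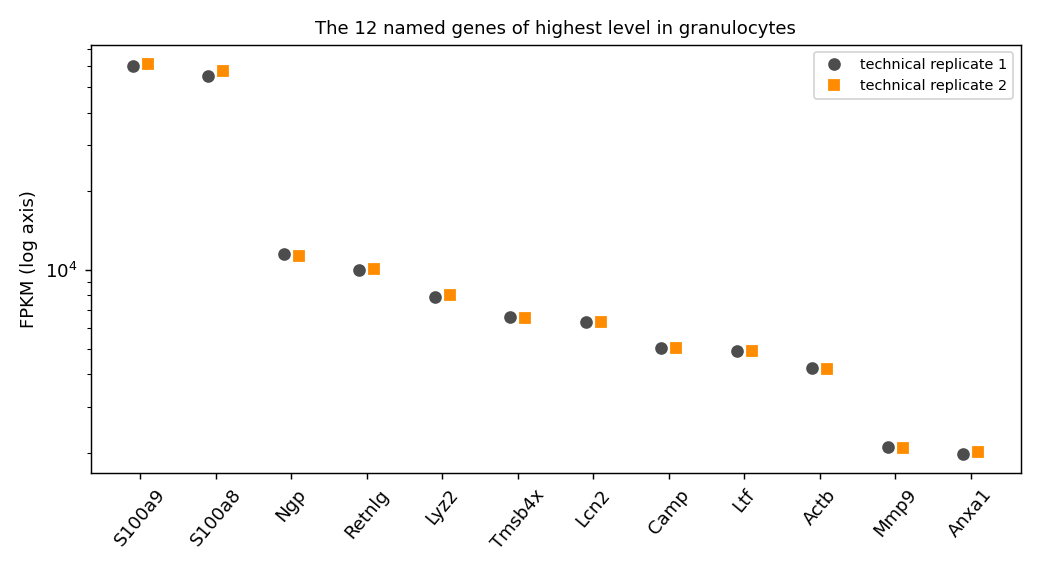
FPKM on a log axis of the 12 named genes of highest mean level in granulocytes, with 1 point for each of 2 technical replicates. S100a9 and S100a8 stand at 60707 and 56391 FPKM on average, and both replicates nearly coincide at every gene.

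Both granulocyte libraries gave nearly the same profile. Over 6057 features at or above the floor, the log2 ratio of the replicates had an SD of 0.06, and 99.9% of the features lay within 1.5-fold. The correlation of log2 values across genes was 0.999; genes are not independent replicates. Among 14453 features with at least 20 reads the median chi-square between the replicates was 0.544, against 0.452 for sampling noise alone, so they differed by slightly more than sampling noise.

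The KSL libraries held the transcripts behind the sort and low to moderate levels of granulocyte genes. Kit was at 67.6 FPKM in the control, 59.1 in the LncHSC-1 and 62.0 in the LncHSC-2 library, and Ly6a, which encodes Sca-1, was at 1010, 1211 and 1025 FPKM. Its neighbour in the same gene family, Ly6e, was at 1124, 1406 and 1203 FPKM. Of the 12 highest granulocyte genes, Lyz2 was at 84.8, Anxa1 at 51.4, S100a8 at 42.5, S100a9 at 36.6, Camp at 1.90 and Mmp9 at 0.450 FPKM in the control KSL library, and Tmsb4x and Actb were at 1374 and 868 FPKM; these values come from another experiment with another FPKM divisor and are set side by side without a fold. Of the 36 mature granulocyte genes 12 reached 5 FPKM in that library, against 38 of the 51 stem cell genes, whose median was 22.4 FPKM. Cd34 was at 229 FPKM there and at 0.940 FPKM in the granulocytes.

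The knockdown libraries were made to look for genes that depend on each long non-coding RNA. Which features of the files are LncHSC-1 and LncHSC-2 is not given in the sources used here, so the depth of each knockdown is not reported. Most named genes were at nearly the same level in all 3 libraries: 99.3% of 7944 lay within 1.5-fold of control in the LncHSC-1 library and 99.7% in the LncHSC-2 library. The E protein gene Tcf3 was at 39.6 FPKM in the control library, 39.9 in the LncHSC-1 library and 38.7 in the LncHSC-2 library.

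The LncHSC-1 library held more transcript of the B lineage list, the monocyte, macrophage and dendritic list and the interferon response list than the control library. Ly6c2, a surface antigen of myeloid cells (chromosome 15, 74938591 to 74942379), was highest, at 101 against 32.5 FPKM (log2 ratio 1.6, counting interval of the reads, without pseudocount, 1.49 to 1.77). The chemokine Cxcl10 was at 137 against 52.2 FPKM (1.38, 1.30 to 1.49), the complement gene Cfb at 9.92 against 3.07 (1.43, 1.47 to 1.93) and Ms4a4c at 60.3 against 23.2 (1.34, 1.27 to 1.49). The chemokine Ccl5 (1.18), the early B cell marker Ly6d (1.10) and Apol9a (1.05) followed. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123276058 to 123371782), was the named gene furthest below control, at 49.2 against 107 FPKM (−1.10, −1.17 to −1.07). The ribosomal RNA precursor feature Rn45s, chosen after its value was seen, was at 109 against 470 FPKM in the same library (−2.10), and the unnamed feature HAG_042880, chosen in the same way, which overlaps Lars2, was at −1.32. The RNA was polyA-selected, so the Rn45s value is no measure of ribosomal RNA in the cells. Whether the lower Lars2 value is separate from that of the overlapping feature was not tested.

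All 8 measured genes of the B lineage list were higher in the LncHSC-1 library, 2 of them by 2-fold or more, with a median log2 ratio of 0.83. The coactivator Pou2af1 was at 17.0 against 6.89 FPKM (1.19), the adaptor Blnk at 9.53 against 4.26 (1.00) and the antigen receptor subunit Cd79a at 22.0 against 11.6 (0.86). The median of the monocyte, macrophage and dendritic list was 0.57, and 10 of its 11 measured genes were higher. Its members furthest from control were the class II presentation genes Cd74 (0.94, in a feature merged with Mir5107), H2-Aa (0.88) and H2-Eb1 (0.73), which B cells also express, and Ly86 (0.67). Its 19 members below the floor stood closer to control, at 0.14 (0.04 to 0.24) for their pooled reads. The pooled reads of 12 B lineage members below the floor stood at 0.92 (0.79 to 1.05). All 37 interferon response genes were higher, 1 of them past 2-fold, with a median of 0.40. Ifit3 was at 48.5 against 25.6 FPKM (0.89), Mx1 at 50.2 against 28.3 (0.80) and the nucleic acid sensor Zbp1 at 154 against 93.7 (0.71).

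The other 7 of the 10 lists above the central range of random lists stood closer to control. T and NK lineage genes had a median of 0.23 over 4 genes, led by Thy1 (0.55), and mature granulocyte genes one of 0.13, with Pglyrp1 at 0.43 and S100a9 at −0.32. Immediate early and stress genes stood at 0.10, led by Egr1 (0.47) and Jund (0.39), and megakaryocyte genes at 0.09, led by the merged feature of Gp1bb and Sept5 (0.50) and Pf4 (0.39). Cytokine signalling genes stood at 0.08, with Tnfrsf13b at 0.48 and Il3ra at 0.44, erythroid genes at 0.07, with Zfpm1 at 0.31, and primary granule genes at 0.07, with Mpo at −0.23. Without the members it shares with other lists, the erythroid median was 0.05 and lay within the range. The mature granulocyte median without shared members was 0.07 and stayed above it. The mean of the primary granule list with all members was 0.03, with 8 of 13 genes higher.

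Cell cycle genes were slightly lower in the LncHSC-1 library. The DNA replication list had a median of −0.10, with 26 of 32 genes lower, among them Hells (−0.28) and Ccne2 (−0.29), while Rrm2 was higher (0.84). The mitosis list had a median of −0.09, with 27 of 34 genes lower, such as Ect2 (−0.31) and Cenpa (−0.31). The stem cell list lay within the range at −0.01, as did lymphoid priming at 0.03, where Ly6d (1.10) and Cd52 (0.86) stood apart. After Lars2, the lowest genes were Trappc2 (−0.61), Dynlt3 (−0.61), Nlk (−0.60), Cyb5d1 (−0.60), Rpl17 (−0.57), Akr1c13 (−0.56) and Bex1 (−0.55).

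By the 2-fold rule 11 named genes were higher and 1 was lower in the LncHSC-1 library; with all features the counts were 58 and 39, and 68 of the 85 unnamed or predicted ones had mean scaled counts under 50. The deposited count columns gave 54 higher and 23 lower, and 35 and 2 among named genes. The 3′ UTRs of Pou2af1 and Dynlt3 carry 7-base sequences whose carriers were lower than other genes in the control library and in the LncHSC-1 library, respectively. Of all searched genes 1.92% and 17.9% carry such sequences, which were chosen with these genes included. Pou2af1 was also higher in the LncHSC-1 than in the LncHSC-2 library, a comparison without the control library. Lars2, Trappc2, Nlk, Cyb5d1, Rpl17, Akr1c13 and Bex1 carry no LncHSC-1 sequence.

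**Figure D2:**
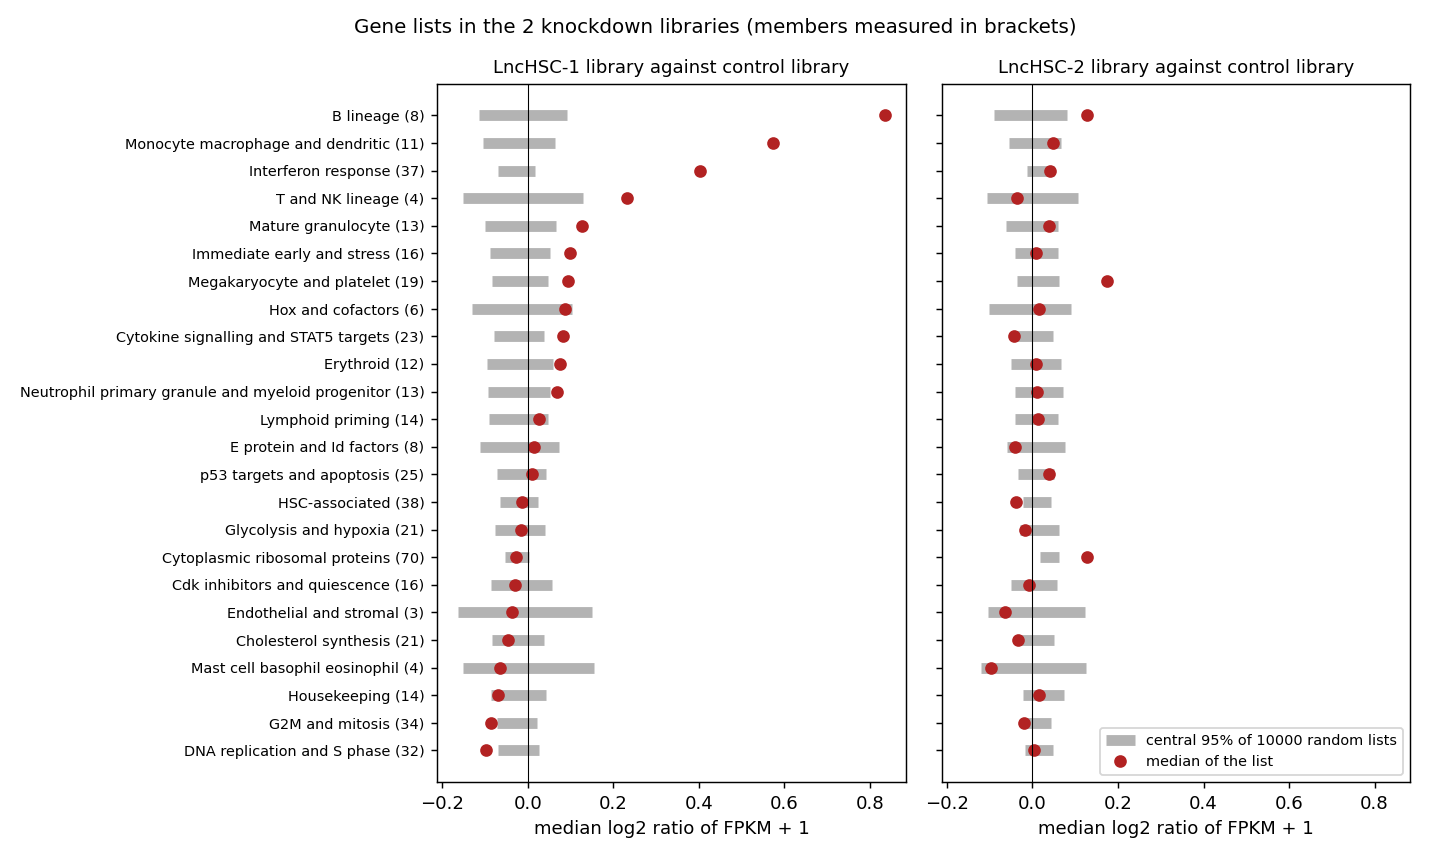
Median log2 ratio of FPKM + 1 (x axis) of the 24 gene lists (y axis, with the number of measured members) in the LncHSC-1 library (left) and the LncHSC-2 library (right) against the control library. Points are list medians and grey bars the central 95% of 10000 random lists; the B lineage list stands at 0.83 on the left and 0.13 on the right.

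The LncHSC-2 library differed from control in fewer genes. Acly, which makes acetyl-CoA for lipid synthesis (chromosome 11, 100337666 to 100389314), was at 37.8 against 77.7 FPKM (log2 ratio −1.02, −1.10 to −0.98), and the S phase cyclin Ccne2 was at 8.56 against 16.1 FPKM (−0.84, −1.06 to −0.77). The general transcription factor gene Gtf2a2 (−0.76), the mitochondrial ribosome gene Mrps21 (−0.75), the chemokine Ccl4 (−0.73) and Ctdspl2 (−0.65) were also lower. Hcst, which encodes a signalling adaptor of natural killer cell receptors (chromosome 7, 31202731 to 31204873), was the only named gene at least 2-fold higher by the main measure, at 25.6 against 12.0 FPKM (1.03, 0.70 to 1.48). Tsen34 (0.97), Zdhhc9 (0.79), Rprd1b (0.77), Pcyox1l (0.77), Rrm2 (0.77), Ydjc (0.70) and Spryd4 (0.69) followed. All 7 of these, and Hcst itself, were also higher in the LncHSC-1 library than in the control library.

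Megakaryocyte and platelet genes were the list furthest above control in the LncHSC-2 library, with a median of 0.17 and 15 of 19 genes higher. The glycoprotein genes Gp9 (0.53) and Gp5 (0.36), the integrin gene Itgb3 (0.30) and the platelet chemokine Pf4 (0.30) led it, and Pf4 stood at 438 against 356 FPKM. This list was also above the range of random lists in the LncHSC-1 library against control (0.09). In LncHSC-1 against LncHSC-2, without the control library, its median lay within the range (−0.05). Cytoplasmic ribosomal protein genes had a median of 0.13, with 66 of 70 higher, such as Rps16 (0.34) and Rps27 (0.31), whereas Rpl12 was at −0.33. The B lineage list stood at 0.13, with Pou2af1 at 0.19. The stem cell list lay slightly below the range at −0.04, with Slamf1 at −0.21 and Msi2 at −0.20, and so did the cytokine signalling list at −0.04, with Pim2 at −0.34 and Id1 at −0.31. Without members shared with other lists, both of these medians were −0.01 and lay within the range, while that of the monocyte, macrophage and dendritic list, 0.05 with all members, was 0.07 and lay above it. The interferon list was at 0.04, within the range, as were the DNA replication list at 0.00 and the mitosis list at −0.02.

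The ribosomal pseudogene Rpsa-ps10 had no read in the LncHSC-2 library against 182 in the control library, at least 57.4-fold lower; HNG_025568, a feature at the same position chosen after its values were seen, had 225 reads against 27.8. Summed over both features the position had 225 reads against 210.0, a log2 ratio of 0.18 whose interval of −0.10 to 0.46 includes 0. Eif3s6-ps2, another pseudogene, was at −0.66 on 22.0 against 39.0 reads, and its interval of −1.57 to 0.05 includes 0. Of the 8 named genes highest in the LncHSC-2 library, all but Ydjc carry a control library 7-base sequence in their 3′ UTRs. Carriers of such a sequence were lower than other genes in the control library and make up 1.92% of all searched genes. Acly, Ccne2, Gtf2a2, Mrps21 and Ctdspl2 carry one whose carriers were slightly lower than other genes in the LncHSC-2 library, as 31.5% of all searched genes do. The sequences of both groups of genes were chosen with the genes themselves included. With sequences chosen in the other part of the genes, 6 of the 20 lowest in the LncHSC-2 library carried one, against 25.7% of all searched genes. By the 2-fold rule 1 named gene was higher and 2 were lower, Acly and Rpsa-ps10; with all features the counts were 55 and 32, and 77 of the 84 unnamed or predicted ones had mean scaled counts under 50. The deposited count columns gave 14 higher and 24 lower, or 19 and 16 after centring, and among named genes 2 and 6, or 5 and 3 after centring.

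**Figure D3:**
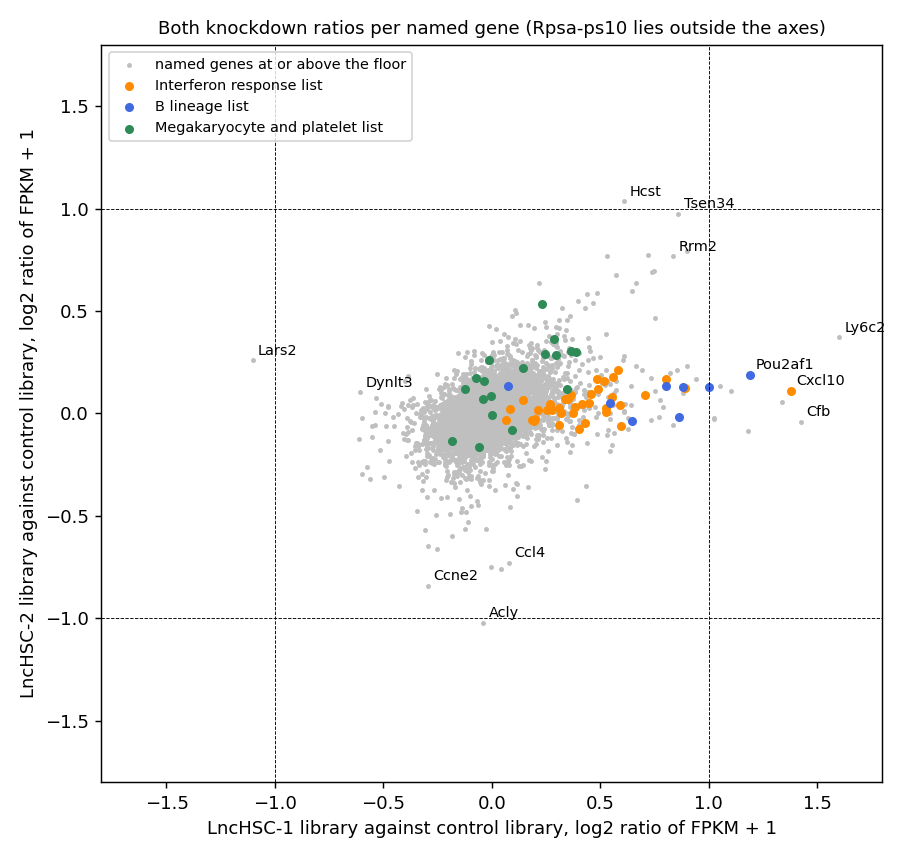
Log2 ratio of FPKM + 1 against the control library in the LncHSC-1 library (x axis) and in the LncHSC-2 library (y axis), 1 point per named gene, with 3 gene lists in colour and dashed lines at 2-fold. Interferon and B lineage genes spread to the right along the x axis, Acly lies at −1.02 on the y axis, and Tsen34 and Rrm2 lie high on both.

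Of the 7944 named genes 66.3% differed from control in the same direction in both knockdown libraries. Simulated libraries without any effect gave 67.1% with Poisson noise and 66.7% with the spread of the 3 libraries taken as replicate error. The genes named here are the extremes of a ranking by the smaller of both ratios. The 5 highest in both were Tsen34, a subunit of the tRNA splicing endonuclease (0.86 and 0.97), the palmitoyltransferase Zdhhc9 (0.90 and 0.79), the ribonucleotide reductase subunit Rrm2 (0.84 and 0.77), Rprd1b (0.72 and 0.77) and Ydjc (0.75 and 0.70). The 5 lowest were the repressor Zfp238 (−0.43 and −0.36), Cryl1 (−0.34 and −0.48), Cxx1c (−0.32 and −0.37), Akr1c13 (−0.56 and −0.32) and Dync2li1 (−0.32 and −0.33). None of them passed 2-fold in both libraries, and the count of named genes past 2-fold in both was 0 in either direction, where 0.001 would be higher in both if the lists were independent. Tsen34, Zdhhc9, Rrm2 and Rprd1b carry a control library 7-base sequence in their 3′ UTRs, as 1.92% of all searched genes do. The sequences were chosen with these genes included, so this is no independent count. With sequences chosen in the other part of the genes, 10 of the 20 highest in both carried one, against 2.00% of all searched genes.

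Over the 7944 named genes the ratios of both knockdowns had a correlation across genes of 0.423 and a covariance of 0.00762. Simulated libraries without any effect gave 0.509 and 0.00194 with Poisson noise, and 0.5001 and 0.00963 with the spread of the 3 libraries taken as replicate error. Over all 9153 features 28 were higher in both and 7 were lower in both, against 0.349 and 0.136 for independent lists. The Poisson simulation gave 13.4 and 11.02, and that with the spread of the 3 libraries 15.39 and 13.23. Of the 28 features 3 had mean scaled counts of at least 50. All or part of the shared direction may come from the single control library, and this design cannot split it.

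Set directly against the LncHSC-2 library, the LncHSC-1 library again held more of the same groups, in a comparison that leaves the control library out. Cfb (1.47), Ms4a4c (1.28), Cxcl10 (1.27) and Ccl5 (1.27) were the highest genes apart from Rpsa-ps10, which had 222 reads and was at least 59.9-fold higher alone, while its position summed with HNG_025568 was at 0.00 (−0.26 to 0.26). The B lineage list had a median of 0.72, with 7 of 8 genes higher, the monocyte and dendritic list 0.43, with 10 of 11, and the interferon list 0.36, with 37 of 37. Ribosomal protein genes were lower in the LncHSC-1 library, with a median of −0.16 and 68 of 70 genes lower, and so were the DNA replication list (−0.10) and the mitosis list (−0.09). Against control the ribosomal list was within the range of random lists in the LncHSC-1 library (−0.03) and above it in the LncHSC-2 library (0.13). Lars2 (−1.36), Dynlt3 (−0.71), Ube2z (−0.61), Nlk (−0.58) and Trmt61b (−0.57) were lowest, and Rn45s was at −2.17.

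In this comparison 9 named genes, Rpsa-ps10 among them, were higher in the LncHSC-1 library and 1 was lower by the 2-fold rule, and over all features 49 were higher and 56 lower. The deposited count columns gave 69 and 22, or 38 and 22 after centring, and among named genes 48 and 2, or 26 and 2. For lists of unrelated genes 1.2 of 24 would lie outside the range of random lists, which is no benchmark here. Of the 24 lists 12 lay above and 3 below that range. Besides the 3 lists named first, these were the T and NK list (0.27, with Thy1 at 0.73), the cytokine signalling list (0.16, with Tnfrsf13b at 0.58), the immediate early list (0.14) and the lymphoid priming list (0.06, with Ly6d at 1.00). The mature granulocyte (0.06), primary granule (0.06), erythroid (0.05), cholesterol synthesis (0.04) and stem cell lists (0.02) were also above. Without members shared with other lists 8 were above, and the mature granulocyte, primary granule, erythroid and stem cell lists lay within the range; the medians of the primary granule list (−0.03) and the stem cell list (−0.0009) were then below 0, and the mean of the primary granule list with all members was −0.01.

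**Figure D4:**
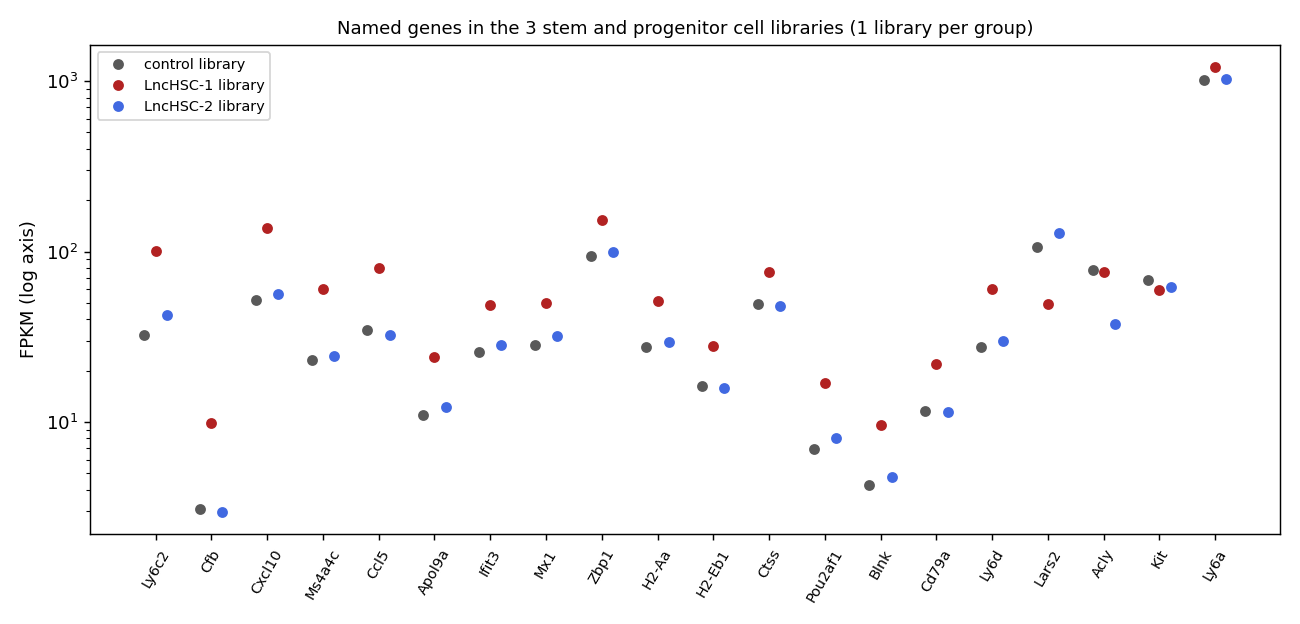
FPKM on a log axis of named genes in the control, LncHSC-1 and LncHSC-2 knockdown libraries, with 1 point per library and no error bar since there is 1 library per group. From Ly6c2 to Ly6d the LncHSC-1 point is the highest of the 3, with Cxcl10 at 137 FPKM against 52.2 in the control library, and Acly is lowest in the LncHSC-2 library at 37.8 FPKM.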

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

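No test in this part was planned or run. The list of cytokine signalling and STAT5 target genes stood above control in the LncHSC-1 library, with a median log2 ratio of 0.081 and 18 of 23 genes higher, and below control in the LncHSC-2 library, with a median of −0.044 and 15 of 23 genes lower. It is named here because the 2 knockdowns lay outside the range of random lists on opposite sides; the difference was not tested, as there is 1 library per group. Members that went opposite ways include the receptor Tnfrsf13b (0.48 and −0.10) and the feedback inhibitor Socs1 (0.18 and −0.23). Id1 was lower in both libraries (−0.34 and −0.31) and Il3ra higher in both (0.44 and 0.26). Without the 9 measured members it shares with other lists, the LncHSC-2 median was −0.01 and lay within the range.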

How the results depend on the processing

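The count column alternatives and the removal of genes with a control library 7-base sequence were chosen after the data were seen. Of 2955 values of named genes under other scalings and pseudocounts 2907 moved by less than the half-width of their counting interval and 47 by more, and 1 whose interval left out 0 changed sign (Bcl11a in LncHSC-1, −0.11 in centred count columns). Of 504 list medians 490 moved by less than the half-width of the range of random lists and 13 by more, and 1 outside their range changed sign (primary granule genes, LncHSC-1 against LncHSC-2, mean −0.015). The correlations of both knockdown ratios lay between 0.382 and 0.515 in all settings. Under median-of-ratios and trimmed mean scaling all counts stayed within 1.5 times; those that moved were LncHSC-1 against LncHSC-2, to 51 higher (named 10) under both, and LncHSC-1, to 38 lower under median-of-ratios. For the others the cause was not tested, except that floors change which genes are counted. Counts are given as higher and lower for LncHSC-1, for LncHSC-2, for LncHSC-1 against LncHSC-2 and for both knockdowns. Without a floor they were 151 and 132, 137 and 128, 133 and 133, and 55 and 60, and among named genes 18 and 3, 4 and 2, 16 and 4, and 1 and 0. With a floor of 1 they were 123 and 98, 110 and 99, 104 and 105, and 52 and 39 (named 18 and 3, 3 and 2, 14 and 3, 1 and 0), and with a floor of 20 they were 17 and 20, 19 and 11, 16 and 27, and 7 and 2 (named 5 and 1, 0 and 1, 4 and 1, 0 and 0). A pseudocount of 5 gave 41 and 25, 43 and 25, 33 and 46, with 4 lower in both (named 5 and 1, 0 and 1, 5 and 1); one of 0.1 gave 2 named genes higher in LncHSC-2. Count columns gave 54 and 23, 14 and 24, 69 and 22, and 10 and 4 (named 35 and 2, 2 and 6, 48 and 2, with 1 higher in both), and centred 55 and 23, 19 and 16, 38 and 22, and 11 and 4 (named 36 and 2, 5 and 3, 26 and 2, with 1 higher in both). Without genes with a control library 7-base sequence 0 named genes were higher in LncHSC-2. Lists below the range in LncHSC-2 numbered 4 by the mean and 1 with a pseudocount of 0.1. The SD between granulocyte replicates was 0.10 at a floor of 1, where low counts add sampling noise.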

Other observations

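The 3 tests of 3′ UTR sequences in this part were written down before their results were seen; all the other tests were chosen after the result was seen. Immunoglobulin transcripts, outside the fixed lists and chosen after their values were seen, went with the B lineage genes of the LncHSC-1 library. The kappa light chain feature was at 520 FPKM there against 247 in the control and 259 in the LncHSC-2 library (log2 ratio 1.07 against control), a lambda light chain feature was at 0.79, a heavy chain feature at 0.81 in FPKM, outside the interval of its reads (0.495 to 0.620), and the joining chain gene Igj at 0.54. Irf7, the regulator of interferon genes, was at 377 against 261 FPKM (0.53) in the LncHSC-1 library and at 265 FPKM in the LncHSC-2 library. It is a member of the fixed interferon response list and is already counted there. Siglech, a plasmacytoid dendritic cell gene, was at 2.998 against 2.22 FPKM, and Ly6c1 at 11.9 against 7.73.

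Reads of Rn45s, the precursor of ribosomal RNA, were fewer in the LncHSC-1 library, at 18262 estimated reads. The control library held 67557 and the LncHSC-2 library 67009, log2 ratios of −2.10 and 0.07. As the RNA was polyA-selected, these reads do not measure the level of ribosomal RNA in the cells. The unnamed features HNG_024632 (−1.21), HND_000993 (−1.29) and HAG_042880 (−1.32), whose nature is not given in the sources used here, were lower with it, while the mitochondrial gene mt-Nd4 was at 0.20.

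For genes lower in 1 KSL library that shared short sequences in their 3′ UTRs, a candidate explanation is that each hairpin also lowers transcripts matching its seed, the short stretch by which small RNAs find targets; the hairpin sequences are not given in the sources used here. In the control library the genes with AGCGATT (110 of 7805) had the lowest z of all 7-base sequences, −13.60, against −4.97 for the lowest of 100 gene shufflings, and the overlapping GCGATTA followed at −12.20. CTGAATA in the LncHSC-1 library, at −6.84 against −4.81, and TCTGTTA in the LncHSC-2 library, at −6.87 against −5.13, also lay below their shufflings, and in the ratio of the other two libraries the 3 sequences had z of −1.31, −0.86 and 0.92; the LncHSC-2 shift is small, a median deviation of −0.0012 in carriers against 0.0178 in other genes. With the 2 lowest sequences chosen in 1 random part of the genes and looked up in the other part, 10 of the 20 genes highest in both knockdowns carried a control library sequence, against 156 of all 7805, so the shared direction of some of them may come from the control hairpin, while an effect of the long non-coding RNAs stays open. In the same way 12 of the 20 genes lowest in the LncHSC-1 library carried one of its sequences, against 17.9% of all genes, and 6 of 20 in the LncHSC-2 library against 25.7%, too near to assign single genes.

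The B lineage and interferon response lists were higher together in the LncHSC-1 library. An effect of the control hairpin is argued against, since the interferon list had a median of 0.36 in LncHSC-1 against LncHSC-2, where random lists lay between −0.08 and −0.01. More B lineage cells among the sorted cells, although the sort removes lineage-positive cells, may account for the B lineage part: apart from the 8 genes behind the list median, the 12 B lineage genes below the floor had 1556 pooled reads against 705, a log2 ratio of 0.92 (0.79 to 1.05), beside 0.17 for T and NK, 0.14 for monocyte, 0.10 for mast cell, 0.34 for erythroid and 0.17 for stromal genes below the floor. For the interferon part this stays open: the summed gain of the interferon list, 1358 FPKM, was 22.16 times that of the B lineage list, 61.3 FPKM, 3.85 times with 3 immunoglobulin features added and 1.99 times with the heavy chain feature too, and the interferon gene level of such B lineage cells was not measured here. An effect of lowering LncHSC-1 on these genes was not tested apart from these explanations, as the group has 1 library. Such an effect would also raise the reads of B lineage genes below the floor, so they cannot tell it from more B lineage cells.

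A pair of unnamed transcript models on chromosome 3, HNG_025534 and HNG_026509 (142679061 to 142737191, mm9), chosen after their values were seen, were lower in the LncHSC-2 library. HNG_025534 had 801 reads there against 2397 in the control and 3030 in the LncHSC-1 library, HNG_026509 had 591 against 1654 and 2219, and both were at 0.03 FPKM in granulocytes. Reassignment of reads between overlapping features was not excluded: the files hold no other feature there, so the summed reads, at a log2 ratio of −1.46 (−1.55 to −1.37), only restate the pattern. A candidate explanation is the LncHSC-2 hairpin lowering its target transcript: among 369 unnamed models with at least 100 mean reads, 2 other loci were at least 2-fold lower in the LncHSC-2 library than in both others, against 4 in the control and 10 in the LncHSC-1 library. Since the position of LncHSC-2 is not given in the sources used here, this cannot be told apart from any other loss of the transcript in that library.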
